A study of Homo sapiens with 32 samples.

How the data were processed

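The deposited data were expression values of 32 Affymetrix HG-U133A 2.0 arrays, one array for each combination of 4 donors, 4 doses of hypochlorous acid (0, 0.4, 1 and 4 mM) and 2 times (2 and 6 h). Per the labels, the RNA was total RNA taken with an RNeasy kit from primary tracheobronchial epithelial cells and was labelled with biotin. The values were array intensity on a linear scale, as deposited, with 1 value for each of 22277 probe sets. Per the submitters' processing notes, the software was GCOS 1.0, and the algorithm, detection calls and filters were not given in the sources used here. All 32 arrays had the same 2%-trimmed mean intensity (500.141 to 500.184), so the authors had scaled the arrays globally. The median intensity per array ran from 106 to 119, the smallest value was 0.0405 and the largest was 37257. The number of arrays, 4 in each of 8 groups, limited the precision. Groups were taken from the sample descriptions, and 1 control sample of 2 h (donor 1) also carries a treatment entry that names HOCl for 2 h.

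Gene symbols came from the array annotation, and symbols were checked against a current gene table by Entrez ID. Of the probe sets, 62 were control probe sets, 19064 named 1 gene, 1043 named several genes and 2108 had none listed. Among the probe sets with 1 gene, 19052 were matched by Entrez ID and 0 symbols needed an update. XIST and Y-linked genes (24 genes) were left out of every test. Where a gene had several probe sets (4304 genes), the one with the highest mean over all 32 arrays was used, which left 11939 genes. No column of the table was left unused. The probe sets with several or no genes listed were tested separately.

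The values were transformed as log2(intensity + 16). A gene was tested if its value was above the array's 40th percentile (44.3 to 57.6 in intensity) on at least 4 of the 32 arrays, which kept 8528 genes. Because of the added constant, fold changes are on the scale of intensity + 16 and understate the changes of genes with low intensity. A linear model was fitted to each gene with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). The model had the 8 groups and the donor as a fixed block, with 21 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Values are given as the fitted log2 fold change ± its standard error, with 4 donors in every group, and intensities as mean ± SD.

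The comparisons were each dose against the control of the same time, the steps between neighbouring doses, the difference of each dose's effect between 6 and 2 h, and the 6 h control against the 2 h control. The donor block rests on the donor codes in the labels, which are the same codes at every dose and time. After group means were removed, arrays of the same donor had a median correlation across genes of 0.591 (112 pairs) and arrays of different donors had a median of -0.112 (336 pairs), with ranges of 0.164 to 0.868 and -0.648 to 0.299. Donor took 53.9% of the variance, time 12.5%, dose within time 8.91% and the residual 24.7%.

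A total of 22 gene lists were written before the data were examined, as were the model, the filter, the thresholds, the comparisons, the alternatives listed below and the rule for named genes. The lists covered NRF2 antioxidant targets, heat shock chaperones, ER stress and the integrated stress response, immediate early genes, NF-kB targets and cytokines, metallothioneins, interferon-stimulated genes, p53 targets, cell cycle, EGFR ligands and wound repair, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, the proteasome, aryl hydrocarbon receptor (AhR) and aldehyde detoxification genes, and markers of secretory, ciliated, basal and squamous epithelial cells, fibroblasts, leukocytes and endothelium. Lists with at least 5 measured members (20 of the 22) were tested with limma's camera at a preset inter-gene correlation of 0.01. The p values were adjusted over the 120 tests of 20 lists in 6 dose comparisons. Each list was tested again with an estimated correlation, and with fry, which asks only whether a list's genes move on balance one way. Members were also called with p values adjusted over the list alone.

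Named genes followed a fixed rule. In each dose comparison these were the up to 10 called genes with the largest rise and the up to 10 with the largest fall among genes that moved the same way in all 4 donors. For each list they were the up to 4 called members with the smallest p, or up to 2 members with the largest change where none was called. For the other comparisons they were up to 5 genes each way. A set of 16 genes was to be given at every dose and time. Of these 13 were tested, SRXN1 and HSPA1A had no probe set naming 1 gene, and MUC5AC was below the filter. Where another called member of a list is named, it was chosen after its values were seen.

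The fit was tested on simulated data for 4 mM against control at 6 h with 8528 genes, in 5 runs. It recovered 57.3% of genes changed by 0.5 log2 units, 91.9% of those changed by 1 and 100% of those changed by 2, and 4.71% of its calls were false. The simulated values followed the fitted model, with independent genes and the same spread on every array. The share of false calls was therefore largely set by the model and does not give the share among the calls in the real data. Alternatives changed one choice at a time: the scaling (quantile normalization or array medians), the added constant (1 or 64), the low-value filter, the donor block, the arrays in the fit, the variance model, array weights, the treatment of several probe sets, and the optical density of the RNA as a covariate. Each donor was left out in turn. The fits without 1 control array or 1 array at 4 mM, which had the largest residual spreads, were added after seeing the data, as was a donor and time block for the differences between times. Arrays were also regrouped in every other way (35 splits of 8 arrays, or 100 drawn splits for the differences between times).

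Called gene counts of comparisons that share control arrays were set beside simulated data with no effect and beside fits in which the donors were divided into separate pairs. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Where a called gene had several probe sets (4, 17, 36, 0, 2 and 86 genes at 0.4, 1 and 4 mM at 2 h and then at 6 h), 0, 1, 1, 0, 0 and 12 of them had a probe set with the opposite sign, and 0 had one called in the opposite direction.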

Results

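Transcript levels were measured in primary human tracheobronchial epithelial cells that had been grown to full differentiation and exposed on their apical side to hypochlorous acid (HOCl), an oxidant made by the myeloperoxidase of neutrophils. Per the labels, cells of 4 donors were each treated with 0, 0.4, 1 and 4 mM HOCl for 2 or 6 h, and whether HOCl was removed before the cells were harvested was not stated there. This gave 8 groups of 4 arrays. The series asked which genes of the airway epithelium respond to HOCl, and the doses and times allowed the responses to be compared by dose and by time. The mean 3' to 5' ratio of GAPDH lay between 0.888 and 0.952 over the groups and that of ACTB between 1.112 and 1.17. The mean optical density of the RNA at 260 nm was 17.5 to 18.3 in the 2 h groups and 23.5 to 26.5 in the 6 h groups. Among 8528 tested genes, 14, 53 and 118 were called against the control at 2 h with 0.4, 1 and 4 mM HOCl. At 6 h 3, 8 and 228 genes were called. These counts rest on an error estimate shared by all arrays, which can be too small for comparisons with the 2 h control. Without the 2 h control array of donor 1 the counts at 2 h were 11, 24 and 99.

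**Figure D1:**
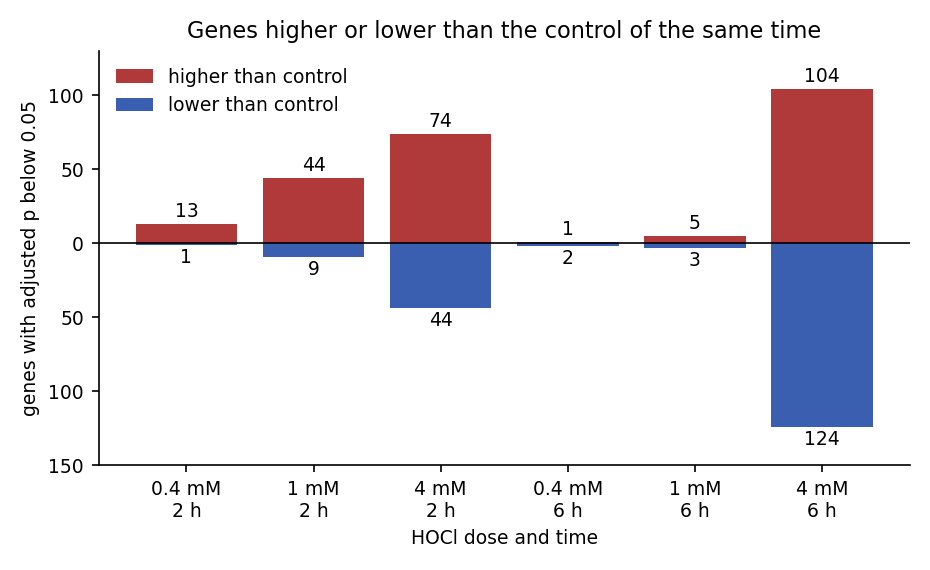
Bars give the number of genes (y axis) with a limma adjusted p below 0.05 against the control of the same time, for each HOCl dose and time (x axis, 4 donors per group), with genes higher than control drawn upward and genes lower than control drawn downward. At 2 h the genes higher than control numbered 13, 44 and 74 with rising dose, and at 6 h the 4 mM dose had 104 higher and 124 lower genes against 5 and 3 at 1 mM.

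With 0.4 mM HOCl at 2 h, the 2 largest rises were those of CYP1A1 and CYP1B1, which are regulated by the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor. CYP1A1, a cytochrome that oxidizes aromatic compounds, rose 22.3-fold (log2 fold change 4.48 ± 0.37, adjusted p = 1.56e-08). Its intensity was 4790 ± 950 against 237 ± 171 in the control (SD, n = 4). CYP1B1, a related cytochrome, rose 5.95-fold (2.57 ± 0.24, adjusted p = 1.14e-07). TIPARP, an ADP-ribosyltransferase that represses the receptor and is under its control, rose 2.43-fold (1.28 ± 0.14, adjusted p = 1.09e-06). Of 30 NF-kB targets and cytokines 2 rose, the epithelial alarm cytokine gene IL1A (1.57 ± 0.23) and PTGS2, the inducible prostaglandin synthase (1.21 ± 0.15). The GTPase gene RND1 (1.33), the kinase gene MAP3K8 (1.06), the growth factor gene ARTN (0.97), HS3ST1 (0.83) and the early response gene IER3 (0.71) also rose. CLTCL1 was the only lower gene (-1.08 ± 0.23), at an intensity of 21.1 against 57. Each of these genes moved the same way in 4 of 4 donors.

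By limma, 14 genes passed in this comparison (13 higher, 1 lower), 8 of them by 2-fold or more, and 730 had an unadjusted p under 0.05, where chance gives 426.4. The AhR and aldehyde detoxification list passed as higher (camera adjusted p = 0.000198, higher in 4 of 4 donors; adjusted p = 0.0231 with an estimated correlation). It had 3 of 15 members called over all genes and 3 adjusted over the list alone, with a mean of 0.591 and a median of 0.053. Its mean rested mostly on CYP1A1, CYP1B1 and TIPARP and not on the list as a whole. Immediate early genes were higher as a group in 4 of 4 donors (mean 0.118, adjusted p = 0.0127), with 1 of 34 called and 2 adjusted over the list alone. Their adjusted p = 0.441 with an estimated correlation. Genes of hypoxia and glycolysis were lower in 4 of 4 donors (mean -0.09, adjusted p = 0.0127), with 0 of 26 called by limma and 0 adjusted over the list alone. Their adjusted p = 0.732 with an estimated correlation, and the call was absent after quantile normalization (adjusted p = 0.0877) and without donor 1 (0.185). Ciliated cell markers passed as higher (mean 0.168, adjusted p = 0.0305), with 0 of 21 called and 0 adjusted over the list alone, but in only 2 of 4 donors. Their adjusted p = 0.899 with an estimated correlation and 0.837 without donor 2.

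The count of 14 genes became 3 without the donor block, 8 with the 2 compared groups alone, 29 with a donor and time block and 35 with array weights. It was 9, 7 and 8 without donors 1, 2 and 3. The log2 fold changes of IL1A and HS3ST1 were 0.67 and 0.52 with the mean of probe sets (0.55 for HS3ST1 without donor 1), and those of RND1 and CLTCL1 were 0.81 and -0.53 with a constant of 64 (-1.69 for CLTCL1 with a constant of 1). None of these 4 genes was called with the smaller value.

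With 1 mM HOCl at 2 h, CYP1A1 and CYP1B1 were the most changed genes, and TIPARP rose with them. CYP1A1 rose 31.1-fold (4.96 ± 0.37, adjusted p = 1.4e-09), CYP1B1 6.92-fold (2.79 ± 0.24) and TIPARP 2.78-fold (1.47 ± 0.14). Of 30 NF-kB targets and cytokines 6 rose, namely IL1A (1.84 ± 0.23), PTGS2 (1.33 ± 0.15), LIF (1.30 ± 0.26), IL1B (1.25 ± 0.30), IL6 (1.04 ± 0.17) and the transcription factor gene IRF1 (0.47 ± 0.11). The EGF receptor ligand gene EREG (1.21 ± 0.28), the growth arrest gene GADD45A (0.64 ± 0.11) and PPP1R15A, a phosphatase subunit of the integrated stress response (0.56 ± 0.11), rose as well. RND1 (1.80), MAP3K8 (1.34), ARTN (1.24) and IER3 (0.84) were higher again. The 9 lower genes included PPP1R3C, which targets a phosphatase to glycogen (-1 ± 0.16), the lipid droplet gene HILPDA (-0.89 ± 0.16) and the bradykinin receptor gene BDKRB2 (-0.78). The others were ENC1 (-0.66), the Wnt inhibitor gene DKK1 (-0.64), TENT5A (-0.60), the MAP kinase phosphatase gene DUSP10 (-0.48), AVPI1 (-0.43) and OVOL2 (-0.41). All 53 called genes moved the same way in 4 of 4 donors.

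The 53 genes were 44 higher and 9 lower, 15 of them changed by 2-fold or more, with 741 at an unadjusted p under 0.05. NF-kB targets and cytokines rose as a group in 4 of 4 donors (mean 0.275, adjusted p = 0.000185; adjusted p = 0.461 with an estimated correlation), with 7 called adjusted over the list alone. The AhR list passed as higher (mean 0.611, adjusted p = 0.000777; adjusted p = 0.0374 with an estimated correlation), with 3 of 15 called and 3 adjusted over the list alone. Its mean again rested on CYP1A1, CYP1B1 and TIPARP. Immediate early genes rose (mean 0.138, adjusted p = 0.00268; adjusted p = 0.336 with an estimated correlation), with 1 of 34 called and 2 adjusted over the list alone. The hypoxia list was lower in 3 of 4 donors (mean -0.091, adjusted p = 0.0226; adjusted p = 0.789 with an estimated correlation), with 0 of 26 called and 0 adjusted over the list alone. Secretory and mucous cell markers were lower in 3 of 4 donors (mean -0.103, adjusted p = 0.0267; adjusted p = 0.822 with an estimated correlation), with 0 of 24 called and 0 adjusted over the list alone. For these last lists quantile normalization gave an adjusted p of 0.136 and 0.372. Single donors also ended their calls, the first without donor 1, 2 or 3 (adjusted p = 0.0728, 0.0761 and 0.083) and the second without donor 1 or 4 (0.0664 and 0.662).

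The count of 53 genes became 3 without the donor block, 22 with the 2 compared groups alone and 108 with array weights. It was 22, 34, 24 and 35 without donors 1 to 4 in turn and 24 without the 2 h control array of donor 1, which had the largest residual spread. The 5 list calls became 3 without donor 1. The log2 fold change of IL1A was 0.86 with the mean of probe sets and that of RND1 1.15 with a constant of 64, and the calls of IL1B, AVPI1 and OVOL2 were made at only 10, 8 and 7 of 21 other settings.

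With 4 mM HOCl at 2 h, antioxidant and stress genes passed beside the AhR and cytokine genes. CYP1A1 rose 41.2-fold (5.36 ± 0.37, adjusted p = 2.11e-10), to an intensity of 8760 ± 1270 (SD, n = 4), and IL1A rose 4.36-fold (2.13 ± 0.23, adjusted p = 4.34e-07), both in 4 of 4 donors. Of 33 NRF2 antioxidant targets 5 rose. They were HMOX1, the heme-degrading oxygenase (1.01 ± 0.22), OSGIN1 (0.91 ± 0.23), MAFG, a partner of NRF2 (0.88 ± 0.18), the cystine transporter gene SLC7A11 (0.85 ± 0.17) and the thioredoxin reductase gene TXNRD1 (0.57 ± 0.08). The largest fall was that of the endothelin gene EDN2, which fell by 2.26 ± 0.41 on the log2 scale (adjusted p = 0.00139, lower in 4 of 4 donors), to an intensity of 116 against 840. Of the 26 genes of hypoxia and glycolysis, the oxygen-sensing hydroxylase gene EGLN3 (-0.91 ± 0.18) and the glycolytic regulator gene PFKFB3 (-0.75 ± 0.17, lower in 3 of 4 donors) fell. HILPDA (-1.36 ± 0.16) and the stanniocalcin gene STC1 (-0.92 ± 0.23) fell too.

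Of 30 NF-kB targets and cytokines 7 rose, with IL1B (1.44), IL6 (1.39), LIF (1.39), PTGS2 (1.34), REL (0.60) and IRF1 (0.44) beside IL1A. Of 34 immediate early genes 4 rose, which were IER3 (1.11), KLF4 (0.71), ZFP36 (0.67) and JUNB (0.51). Among 19 p53 targets GADD45A (0.94) and the cell cycle inhibitor gene CDKN1A (0.44) rose while SESN1 (-0.39) and PLK2 (-0.36) fell. In the EGFR and wound repair list EREG (1.56) rose while the collagenase gene MMP13 (-0.73) and STC1 fell. The integrated stress response list had 1 riser, PPP1R15A (0.87), and the heat shock list had 1, the co-chaperone gene DNAJB1 (0.45). CYP1B1 (2.81), MAP3K8 (1.79), RND1 (1.73), TIPARP (1.65), GPER1 (1.5), ARTN (1.48) and the Wnt receptor gene FZD10 (1.47) completed the largest rises. PPP1R3C (-1.46), DKK1 (-1.02), CH25H (-0.89), TENT5A (-0.89), DUSP10 (-0.82) and FAM13A (-0.79) completed the largest falls.

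In total 118 genes passed (74 higher, 44 lower), 114 of them in the same direction in 4 of 4 donors and 29 by 2-fold or more, with 929 at an unadjusted p under 0.05. NF-kB targets rose as a group (mean 0.389, adjusted p = 2.61e-08; adjusted p = 0.216 with an estimated correlation), with 9 called adjusted over the list alone. Immediate early genes rose (mean 0.185, adjusted p = 1.73e-05; adjusted p = 0.0908 with an estimated correlation), with 6 called adjusted over the list alone. The AhR list passed as higher (mean 0.651, adjusted p = 0.00125; adjusted p = 0.0416 with an estimated correlation), with 3 of 15 called and 3 adjusted over the list alone. Its mean rested on CYP1A1, CYP1B1 and TIPARP here too. The hypoxia list fell (mean -0.165, adjusted p = 0.00125; adjusted p = 0.543 with an estimated correlation), with 4 called lower adjusted over the list alone. These 4 lists moved the same way in 4 of 4 donors. Secretory and mucous cell markers fell in 3 of 4 donors (mean -0.164, adjusted p = 0.00568), with 0 of 24 called and 0 adjusted over the list alone. Their adjusted p = 0.659 with an estimated correlation and 0.875 without donor 4. The NRF2 list did not pass as a group (adjusted p = 0.0983, mean 0.117, median -0.022), with 5 higher and 1 lower adjusted over the list alone. The heat shock chaperones did not pass either (adjusted p = 0.0973), with 5 higher adjusted over the list alone.

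The count of 118 genes became 16 without the donor block, 40 with the 2 compared groups alone and 205 with array weights. It was 53, 67 and 62 without donors 1, 2 and 3, and the 5 list calls became 8 without donor 1. With the mean of probe sets the log2 fold changes of IL1A and REL were 1.01 and 0.38, with a constant of 64 that of RND1 was 1.14, with array weights that of GPER1 was 0.98, and without donor 2 that of HMOX1 was 0.66. REL and HMOX1 were then not called. The call of KLF4 was made at only 10 of 21 other settings.

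**Figure D2:**
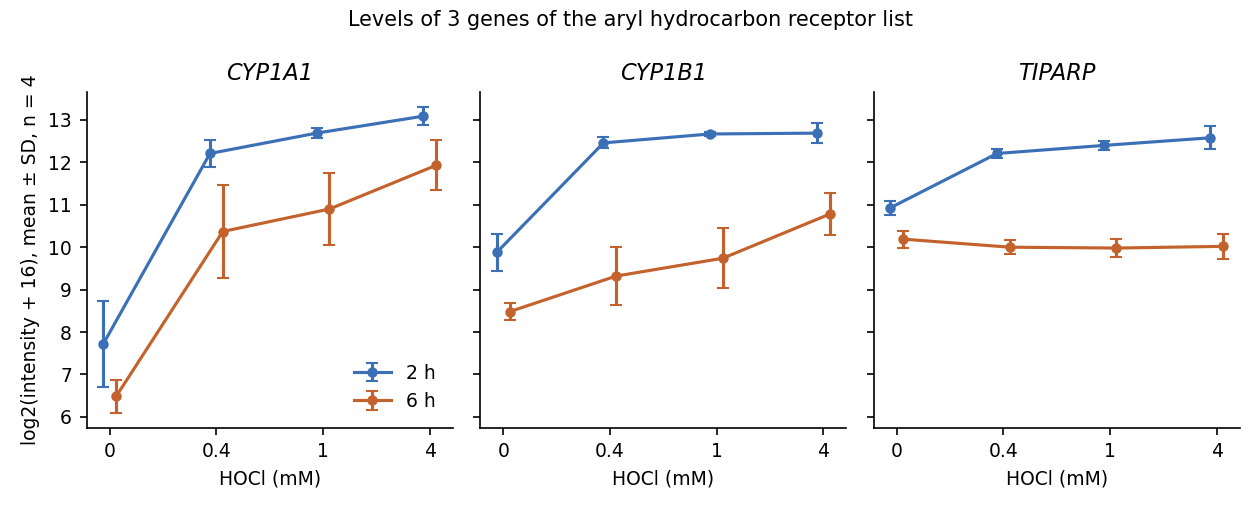
Points and error bars give the mean ± SD over 4 donors of log2(intensity + 16) (y axis) for CYP1A1, CYP1B1 and TIPARP at each HOCl dose in mM (x axis, evenly spaced categories), at 2 h in blue and at 6 h in orange. CYP1A1 was 22.3-fold to 41.2-fold above control at 2 h and 14.8-fold to 43.6-fold at 6 h, while TIPARP lay above control at 2 h and had intensities of 1000 to 1040 against 1160 in the control at 6 h.

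Steps between neighbouring doses were tested directly. At 2 h limma called 0 genes between 0.4 and 1 mM, with 210 at an unadjusted p under 0.05, and 0 between 1 and 4 mM, with 254. Both numbers lay below the 426.4 of chance, so the 0 calls are no evidence that neighbouring doses acted alike. The residual spread (SD) was 0.182 to 0.296 over the 2 h control arrays and 0.144 to 0.208 over the treated 2 h arrays. A shared error estimate can then be too large for steps between doses and too small for comparisons with the 2 h control. With array weights 2 genes passed between 1 and 4 mM, and 4 passed without donor 4. The called genes overlapped between doses. Of the 14 genes called at 0.4 mM, 13 were called in the same direction at 1 mM and 13 at 4 mM, and of the 53 called at 1 mM, 44 were called in the same direction at 4 mM (36 higher, 8 lower). Independent lists of these sizes would share 0.382 higher and 0.0464 lower genes for 1 and 4 mM, 0.0671 and 0.00106 for 0.4 and 1 mM, and 0.113 and 0.00516 for 0.4 and 4 mM.

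These comparisons shared their 4 control arrays. Data simulated without any effect gave a correlation of fold changes across genes, which are not independent replicates, of 0.502 for 1 and 4 mM, where 0.773 was observed. The covariance was 0.0132 in the simulated and 0.0345 in the observed data. For 0.4 and 1 mM the simulated and observed correlations were 0.501 and 0.75, and for 0.4 and 4 mM they were 0.499 and 0.692. The simulation gave every array the same spread for a gene, whereas residual spreads reached higher values over the 2 h control arrays than over the treated ones. Control arrays that vary more raise such a correlation, so the simulated values can be too low at 2 h. With separate donors for each dose, the correlation for 1 and 4 mM was 0.192 on average (0.105 to 0.243 over 6 divisions of the donors), and 8 to 15 genes were called in the same direction. For 0.4 and 1 mM it was 0.161 (0.077 to 0.243) with 4 to 7 shared genes, and for 0.4 and 4 mM 0.141 (0.101 to 0.223) with 4 to 10. CYP1A1, CYP1B1 and TIPARP were shared in all 6 divisions for each pair of doses, and PTGS2 and LPAR6 also for 1 and 4 mM. This set was named after its values were seen.

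With 4 mM HOCl at 6 h, 11 of 33 NRF2 antioxidant targets rose and 0 fell. SLC7A11 rose 2.68-fold (1.42 ± 0.17, adjusted p = 7.15e-06), and HMOX1 rose 2.61-fold (1.39 ± 0.22, adjusted p = 0.00038), to an intensity of 1860 ± 1030 against 645 ± 277 (SD, n = 4). GCLM, a subunit of the rate-limiting enzyme of glutathione synthesis, rose 2.02-fold (1.02 ± 0.08, adjusted p = 1.4e-09), TXNRD1 2-fold (1 ± 0.08) and the quinone reductase gene NQO1 1.91-fold (0.93 ± 0.13). These 5 genes were higher in 4 of 4 donors. OSGIN1 (0.85), SQSTM1 (0.49), TRIM16 (0.38), PGD (0.36), GCLC (0.31) and TALDO1 (0.24) rose as well. CYP1A1 was 43.6-fold above its control intensity of 75.7 ± 23.5 (5.45 ± 0.37, adjusted p = 1.45e-10), and CYP1B1 rose 4.93-fold. The intensity of CYP1A1 with 4 mM was 4160 ± 1980 at 6 h, lower than the 8760 ± 1270 at 2 h, where the control had 237 ± 171. HSPA6, a stress-inducible chaperone gene, rose 5.01-fold (2.32 ± 0.40, adjusted p = 0.000873), with 1.11 to 4.06 on the log2 scale over the donors.

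Of 28 interferon-stimulated genes 6 fell. The chemokine gene CXCL10 (-1.15 ± 0.26), the antiviral genes RSAD2 (-1.01 ± 0.21) and IFIT1 (-0.98 ± 0.19), HERC5 (-0.97 ± 0.16) and IFI44 (-0.64 ± 0.09) were lower in 4 of 4 donors, and the last of the 6 was IFIT3 (-0.71 ± 0.16). The amino acid transporter gene SLC7A5 rose 3.2-fold (1.68 ± 0.19, adjusted p = 1.59e-06). Its partner SLC3A2 (0.87 ± 0.11) and the pseudokinase gene TRIB3 (0.56) were the 2 of 31 members of the ER and integrated stress response list that rose. The remaining largest rises were in genes of low intensity, which were the tachykinin precursor gene TAC1 (85 against 1.87), CD7 (90.9 against 25), the fructose kinase gene KHK (47.1 against 7.13) and STC2 (138 against 48.2). The remaining largest falls were those of CLIC5 (-1.13 ± 0.13), PLCE1 (-1.07), PROM1 (-1.05), SCAPER (-0.94), ESRRG (-0.92) and the bicarbonate transporter gene SLC4A4 (-0.91). Single members of further lists rose, namely PLAT of wound repair (0.77), PFKFB4 of hypoxia and glycolysis (0.95), SERPINH1 of the heat shock list (0.40) and ALDH3A1 of the AhR and aldehyde list (0.52).

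In total 228 genes passed (104 higher, 124 lower), 219 of them in the same direction in 4 of 4 donors and 17 by 2-fold or more, with 1441 at an unadjusted p under 0.05. The NRF2 list rose as a group (mean 0.331, adjusted p = 1.35e-13; adjusted p = 0.0231 with an estimated correlation), with 16 called adjusted over the list alone. The heat shock chaperones rose (mean 0.261, adjusted p = 0.000249; adjusted p = 0.0908 with an estimated correlation), with 2 of 22 called and 4 adjusted over the list alone. The interferon list fell (mean -0.391, adjusted p = 2.93e-09; adjusted p = 0.171 with an estimated correlation), with 12 called adjusted over the list alone. NF-kB targets fell (mean -0.246, adjusted p = 0.000124; adjusted p = 0.461 with an estimated correlation), with 0 of 30 called and 2 adjusted over the list alone. Secretory and mucous cell markers fell (mean -0.186, adjusted p = 0.0157), with 0 of 24 called and 0 adjusted over the list alone. Their adjusted p = 0.764 with an estimated correlation and 0.179 without donor 4. These 5 lists moved the same way in 4 of 4 donors.

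The proteasome list was higher in 3 of 4 donors at this dose and time (mean 0.067, adjusted p = 0.014), with 0 of 27 called and 0 adjusted over the list alone. Its adjusted p = 0.761 with an estimated correlation, and 0.185, 0.0559 and 0.127 without donors 1, 2 and 4. The AhR list did not pass (adjusted p = 0.0983), with 3 of 15 called and 4 adjusted over the list alone, and its mean of 0.506 and median of -0.025 differed in sign. The count of 228 genes became 11 without the donor block, 30 with the 2 compared groups alone and 405 with a donor and time block. It was 78, 80 and 68 without donors 1, 2 and 3, and 345 without the 2 h control array of donor 1.

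Several of the fold changes named for 4 mM at 6 h depended on the probe sets used or on the added constant. With the mean of probe sets the log2 fold changes were -0.74 for CLIC5, -0.40 for PLCE1, -0.38 for SCAPER and -0.59 for ESRRG, and without donor 4 that of SLC4A4 was -0.55. PLCE1, SCAPER and ESRRG were then not called. With a constant of 64 they were 0.99 for TAC1, 0.76 for CD7, 0.61 for KHK, 0.84 for STC2, 0.49 for PFKFB4 and -0.59 for ESRRG. With a constant of 1 they were 4.46 for TAC1, 2.11 for CD7, 2.34 for KHK and 1.45 for PFKFB4, the last of which was then not called.

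**Figure D3:**
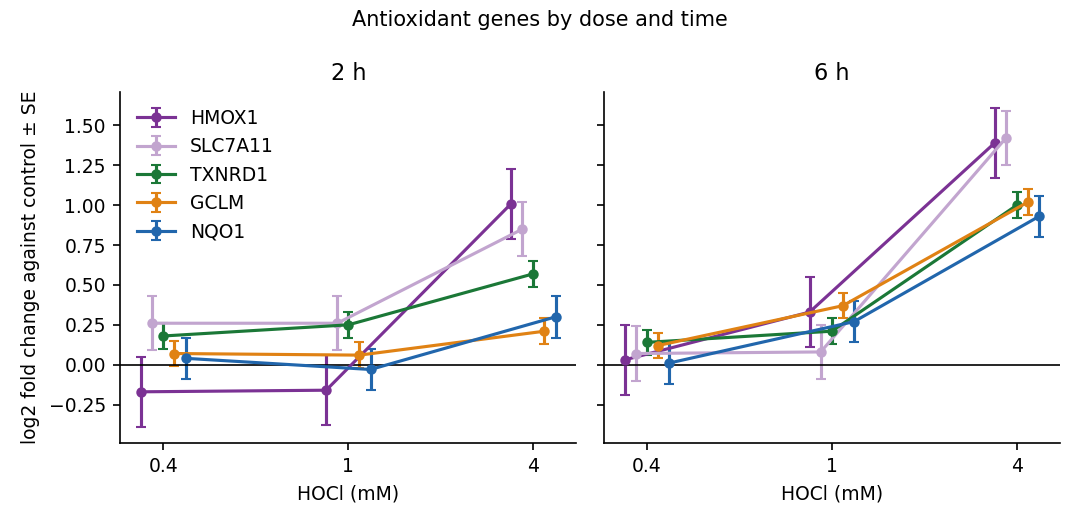
Points and error bars give the fitted log2 fold change against the control of the same time ± SE (y axis, 4 donors per group) for HMOX1, SLC7A11, TXNRD1, GCLM and NQO1 at each HOCl dose in mM (x axis, evenly spaced categories), at 2 h on the left and 6 h on the right. At 4 mM the values were 0.93 to 1.42 at 6 h and 0.21 to 1.01 at 2 h, where GCLM and NQO1 did not pass the test.

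With 1 mM HOCl at 6 h, CYP1A1 rose 21.5-fold (4.42 ± 0.37, adjusted p = 2.12e-08) and CYP1B1 2.4-fold (1.26 ± 0.24, adjusted p = 0.0263). The melanosome protein gene OCA2 (1.10 ± 0.17), SLC7A5 (0.92 ± 0.19) and MDFI (0.63 ± 0.13) rose. The antiviral helicase gene DDX60 (-0.78 ± 0.10), KIAA0513 (-0.61 ± 0.13) and the interferon-stimulated gene IFI44 (-0.52 ± 0.09) fell. These were all 8 called genes, each moved the same way in 4 of 4 donors and 3 by 2-fold or more, with 500 at an unadjusted p under 0.05. Interferon-stimulated genes fell as a group in 4 of 4 donors (mean -0.219, adjusted p = 1.5e-06; adjusted p = 0.336 with an estimated correlation), with 1 of 28 called and 5 adjusted over the list alone. The proteasome list was higher in 4 of 4 donors (mean 0.059, adjusted p = 0.000345; adjusted p = 0.461 with an estimated correlation), with 0 of 27 called and 0 adjusted over the list alone. The NRF2 list was higher in 3 of 4 donors (mean 0.058, adjusted p = 0.0122; adjusted p = 0.543 with an estimated correlation), with 0 of 33 called and 1 adjusted over the list alone. GCLM had 0.37 ± 0.08 (adjusted p = 0.0794, higher in 4 of 4 donors). The AhR list did not pass (adjusted p = 0.102, mean 0.336, median -0.061), with 2 of 15 called and 4 adjusted over the list alone.

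The NRF2 call at 1 mM was absent without donors 1 and 2 in turn (adjusted p = 0.0974 and 0.0643). The count of 8 genes became 2 without the donor block, 13 with a donor and time block, 17 with array weights and 4 or 5 with 6 further settings, and it was 2, 4 and 2 without donors 1, 2 and 3. The 3 list calls became 5 without donor 4. The call of KIAA0513 was made at only 4 of 21 other settings.

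With 0.4 mM HOCl at 6 h, CYP1A1 rose 14.8-fold (3.88 ± 0.37, adjusted p = 4.06e-07), to an intensity of 1660 ± 1480 against 75.7 ± 23.5 (SD, n = 4). HERC5, an interferon-induced ligase gene (-0.84 ± 0.16, adjusted p = 0.0342), and DDX60 (-0.59 ± 0.10, adjusted p = 0.0115) fell. These 3 called genes moved the same way in 4 of 4 donors, and 313 genes had an unadjusted p under 0.05, fewer than the 426.4 of chance. Interferon-stimulated genes fell as a group in 4 of 4 donors (mean -0.228, adjusted p = 2.61e-08; adjusted p = 0.216 with an estimated correlation), with 1 of 28 called and 4 adjusted over the list alone. The proteasome list (mean 0.049, adjusted p = 0.00125, 3 of 4 donors), cholesterol synthesis (mean 0.073, adjusted p = 0.0122, 4 of 4 donors) and metallothioneins (mean 0.109, adjusted p = 0.02, 4 of 4 donors) passed as higher. They had 0 of 27, 0 of 20 and 0 of 8 members called by limma and 0 adjusted over the list alone. Their adjusted p = 0.543, 0.39 and 0.441 with an estimated correlation. The AhR list did not pass (adjusted p = 0.0973, mean 0.279), with 1 of 15 called and 3 adjusted over the list alone.

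Leaving out single donors ended the calls of the proteasome (without donor 3, adjusted p = 0.139), cholesterol (without donor 4, 0.179) and metallothionein lists (without donors 3 and 4 in turn, 0.231 and 0.127), and quantile normalization ended the last (0.183). The count of 3 genes became 1 without the donor block, 7 with a donor and time block and 5 with a constant of 64, and it was 1 without donor 2 or donor 3.

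**Figure D4:**
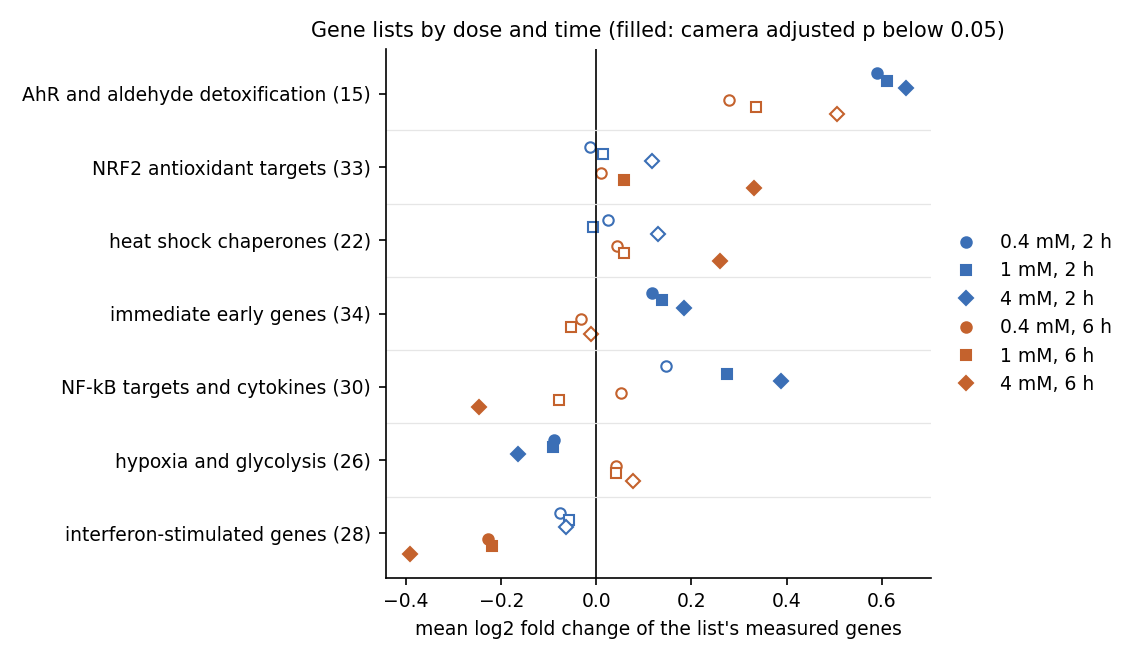
Symbols give the mean log2 fold change against the control of the same time (x axis) over the measured genes (number in brackets) of 7 gene lists (y axis) for each HOCl dose at 2 h (blue) and 6 h (orange), and filled symbols passed limma's camera at an adjusted p below 0.05 with the preset correlation. The interferon list lay at -0.228, -0.219 and -0.391 at 6 h, and the NF-kB list at 0.389 with 4 mM at 2 h and at -0.246 with 4 mM at 6 h.

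Between 1 and 4 mM at 6 h, 8 genes passed (7 higher, 1 lower), with 810 at an unadjusted p under 0.05. The antioxidant genes TXNRD1 (0.79 ± 0.08, adjusted p = 8.39e-07), SLC7A11 (1.35 ± 0.17, adjusted p = 5.54e-05) and NQO1 (0.66 ± 0.13, adjusted p = 0.0225) rose in 4 of 4 donors. HSPA6 (2.16 ± 0.40, adjusted p = 0.017) and STC2 (1.11 ± 0.22, adjusted p = 0.0389) rose as well, and the methyltransferase gene SMYD3 fell (-0.61 ± 0.13). Between 0.4 and 1 mM at 6 h limma called 0 genes, with 196 at an unadjusted p under 0.05, fewer than the 426.4 of chance. At 6 h 2 genes were called in the same direction at 0.4 and 1 mM, 3 at 0.4 and 4 mM and 8 at 1 and 4 mM. The correlations across genes were 0.64, 0.554 and 0.626, where shared controls alone gave 0.499, 0.498 and 0.497 in simulated data. With separate donors for 1 and 4 mM the correlation was 0.187 on average (0.128 to 0.238) and 1 to 4 genes were shared, CYP1A1 in all 6 divisions. The count between 1 and 4 mM became 1 without the donor block, 18 with a donor and time block and 19 with array weights. It was 5, 5 and 3 without donors 1, 2 and 3, and 5 without the 4 mM array of donor 3. The calls of STC2 and SMYD3 were made at only 9 and 10 of 21 other settings.

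The effect of HOCl differed between 2 and 6 h for several of the genes that rose at 2 h. For TIPARP the effect at 6 h was lower by a log2 difference of -1.47 ± 0.19 at 0.4 mM (adjusted p = 0.000207), -1.68 ± 0.19 at 1 mM and -1.83 ± 0.19 at 4 mM (adjusted p = 1.28e-06), in 4 of 4 donors each. PTGS2 differed by -1.08 ± 0.21 and -1.44 ± 0.21 at 0.4 and 1 mM, and the lysophosphatidic acid receptor gene LPAR6 by -0.94 ± 0.14 at 0.4 mM. IL1A differed by -1.67 ± 0.32 and -2.30 ± 0.32 at 1 and 4 mM. MAP3K8 (-1.44 and -2.45) and RND1 (-1.85 and -2.30) differed in the same direction at 1 and 4 mM, and FZD10 (-1.83) at 4 mM. The difference was positive for PPP1R3C (1.04 and 1.33) and MDFI (0.84 and 1.02) at 1 and 4 mM. At 4 mM it was also positive for DKK1 (1.31), PLCXD1 (1.01) and TENT5A (0.93). PPP1R3C had fallen at 2 h (-1 and -1.46), and its mean log2 levels at 6 h were 8.39 and 8.21 against 8.35 in the control. TENT5A (-0.89) and DKK1 (-1.02) had also fallen at 2 h with 4 mM, and at 6 h lay at 10.98 against 10.93 and 10.29 against 10. MDFI (7.89 and 8.16 against 7.26) and PLCXD1 (7.15 against 6.53) lay above the control at 6 h. With the mean of probe sets the differences of IL1A were -0.81 and -1.19 at 1 and 4 mM. With a constant of 64 those of RND1 were -1.15 and -1.43, and that of FZD10 at 4 mM was -1.20. At 1 mM neither IL1A nor RND1 was called at these settings. The call of PPP1R3C at 1 mM was made at only 10 of 21 other settings.

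These tests called 3, 16 and 41 genes at 0.4, 1 and 4 mM (0, 2 and 8 of them with a positive difference), with 589, 514 and 863 at an unadjusted p under 0.05. Differences between times were not tested for lists. Across times, 1, 2 and 11 genes were called in the same direction at 0.4, 1 and 4 mM, and 2 in opposite directions at 4 mM. Independent lists would share 0.902 higher and 0.64 lower genes at 4 mM. The correlation of fold changes across genes was 0.029, 0.145 and 0.258, where simulated data without effects gave -0.001, -0.002 and -0.001 because no arrays are shared. The counts were 1, 1 and 2 without the donor block, 8, 28 and 92 with a donor and time block and 5, 28 and 70 with array weights. At 0.4 mM limma called 0 genes without donor 1, with 375 genes at an unadjusted p under 0.05. At 1 mM it was 4, 10 and 4 without donors 1, 2 and 3, 8 with the compared groups alone, 10 without the 2 h control array of donor 1 and 10 with every probe set. At 4 mM it was 27 and 18 without donors 2 and 3 and 25 with the compared groups alone.

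Between the untreated cultures of 2 h and 6 h, 1604 genes differed (770 higher and 834 lower at 6 h, 59 by 2-fold or more), with 2727 at an unadjusted p under 0.05. CYP26A1, which degrades retinoic acid, was the most changed gene and fell by 5.14 ± 0.30 on the log2 scale (adjusted p = 1.63e-12, lower in 4 of 4 donors). Its intensity was 34 ± 14.7 against 1710 ± 253 at 2 h (SD, n = 4). The actin-bundling protein gene FSCN1 (-1.88 ± 0.35) and the replication genes MCM6 (-1.64 ± 0.17) and DTL (-1.52 ± 0.15) fell. The AhR genes CYP1B1 (-1.41 ± 0.24), CYP1A1 (-1.24 ± 0.37) and TIPARP (-0.74 ± 0.14) fell too. The interferon-induced genes CXCL10 (2.14 ± 0.26), RSAD2 (1.77 ± 0.21) and CXCL11 (1.57 ± 0.29), the collagenase gene MMP13 (1.72 ± 0.19) and the keratin gene KRT16 (1.63 ± 0.16) rose most. The optical density of the RNA was 18 and 26.3 in these groups, and with it as a covariate the count was 683. The count was 364 without the donor block, 532 with the 2 compared groups alone, and 774 and 1008 without donors 1 and 2.

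Of the genes fixed for report at every dose and time, 6 did not pass in any of the 6 dose comparisons. The neutrophil chemokine gene CXCL8 had an intensity of 10000 ± 2400 in the 2 h control (SD, n = 4) and log2 fold changes of -0.32 to 0.03 that did not pass at any dose or time. The stress transcription factor genes ATF3 (-0.10 to 0.50) and DDIT3 (-0.07 to 0.26) did not pass, and the smallest adjusted p of ATF3 was 0.0711, with 4 mM at 2 h, where it was higher in 3 of 4 donors. The metallothionein gene MT1X (-0.26 to 0.06), the ciliated cell regulator gene FOXJ1 (-0.70 to 0.38, SE 0.39) and the basal keratin gene KRT5 (-0.04 to 0.09) did not pass either.

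In the 6 dose comparisons 8 lists never passed. Their smallest adjusted p were 0.194 for ER stress and the integrated stress response, 0.351 for p53 targets, 0.0973 for the cell cycle and 0.706 for EGFR ligands and wound repair. They were 0.0983 for oxidative phosphorylation, 0.709 for basal cell markers, 0.46 for squamous markers and 0.709 for fibroblast markers. Leukocyte markers (3 measured) had means of -0.187 to -0.112 at 2 h and 0.093 to 0.246 at 6 h, and endothelial markers (2 measured) had means of -0.192 to 0.209, neither with a test. Mean, median and test differed in sign in 19 of the 120 list tests and in 0 of those that passed.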

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

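All tests of explanations in this part were chosen after the results they address had been seen. A single donor or array far from the other 3 of its group was looked for in 64 groups of array measures, 182 groups of gene fold changes and 132 groups of list means. Chance gives about 1 in 20 such groups, that is 3.2, 9.1 and 6.6, and 5, 12 and 7 were found.

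The first pattern weighed was the rise of CYP1A1, CYP1B1 and TIPARP at all 3 doses at 2 h. Scaling between arrays was argued against, since under the other scalings the fold changes kept at least 0.996 of their size, and so was low signal with the constant added before the log, since 9 of 9 calls were made with a constant of 64. The labels name no handling step shared by all treated wells and absent from control wells, but one that acted alike at every dose was not excluded at 2 h, where 4 mM exceeded 0.4 mM by 0.98 standard errors for CYP1B1, 2.35 for CYP1A1 and 2.76 for TIPARP (adjusted p = 1, 0.783 and 0.579). At 6 h 4 mM exceeded 0.4 mM by a log2 difference of 1.46 for CYP1B1 (6.02 standard errors, adjusted p = 0.00171), 1.56 for CYP1A1 (4.17 standard errors, adjusted p = 0.0658) and 0.02 for TIPARP (0.14 standard errors, adjusted p = 0.975). A response of these genes to HOCl, the difference the design names, may account for the pattern, and the rise with dose at 6 h is not what a step alike at every dose gives for CYP1B1 at that time.

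The second pattern weighed was the lower level of interferon-stimulated genes with 4 mM HOCl at 6 h. A single deviating array was argued against, since the list mean was -0.317 or lower with any 1 donor left out, and scaling was argued against, since the mean was -0.401 or lower under the other scalings. High interferon signal in the 6 h control arrays alone was argued against only for the step from the other doses to 4 mM. There 4 mM lay below 1 mM in 4 of 4 donors (mean -0.172, SD 0.129) and below 0.4 mM by -0.163 (SD 0.103). This argument is weak, since both steps use the same 4 mM arrays of 4 donors and no list test was run for them. For the rest of the fall high interferon signal in the controls stayed open, since 0.4 and 1 mM lay below the same control arrays by similar amounts. The controls rose between the times by 0.498 (SD 0.321), and the difference of 4 mM at 6 h from the 2 h control was 0.107 (SD 0.165), with 1 of 4 donors lower. A lower interferon signal after HOCl may therefore be a hypothesis for these cells, but the list test gave an adjusted p = 0.171 with an estimated correlation.

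The third pattern weighed was the likeness of fold changes at all 3 doses at 2 h, measured against shared control arrays. With all donors 44 genes were called the same way at 1 and 4 mM. In each division of the donors into separate pairs 8 to 15 of all tested genes were called so, and how many of them were among the 44 was not counted. CYP1A1, CYP1B1, TIPARP, PTGS2 and LPAR6 were called so in all 6 divisions, and for them chance spread of the shared control arrays was argued against. For the other genes called at both doses it was not. For all genes together the correlation was positive in every division (0.077 to 0.243) and the observed values exceeded the highest simulated one (0.543), but the explanation stayed open. The lowest correlation for 0.4 and 1 mM, 0.077, lay within the -0.097 to 0.085 that the same divisions gave for 0.4 mM at 2 against 6 h, those of the other pairs (0.101 and 0.105) lay little above it, and the simulated genes were independent of each other. The simulated arrays also had equal spread, so the simulated correlations can be too low where the control arrays vary more than the treated ones. The control array of donor 1 at 2 h stayed open as a contributor, since the correlations were 0.652 to 0.75 without it, 0.692 to 0.773 with it and 0.748 to 0.827 without each of the other 2 h control arrays, while a response to HOCl alike at the 3 doses may add to the likeness and was not separated from these.

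Array measures stood apart in 5 groups. The 3' to 5' ratio of GAPDH was 0.8593 in the 2 h control of donor 3 (others 0.9249 to 0.9341), 0.9155 with 4 mM at 2 h in donor 4 (others 0.9073 to 0.9084) and 0.8687 with 1 mM at 6 h in donor 4 (others 0.945 to 0.9497). That of ACTB was 1.07 with 4 mM at 2 h in donor 4 (others 1.164 to 1.176). The 100 brightest probe sets held 14.29% of the signal in the 2 h control of donor 1 (others 10.2 to 10.75).

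Single donors stood apart in the log2 fold change of named genes. With 0.4 mM at 2 h, donor 1 had 1.67 for HS3ST1 (others 0.47 to 0.65), 0.37 for GCLM (others -0.06 to 0) and -0.37 for DDIT3 (others 0.34 to 0.44). At the same dose and time donor 4 had 0.73 for MAP3K8 (others 1.14 to 1.19) and donor 3 had 0.07 for TXNRD1 (others 0.21 to 0.23). For PPP1R15A at 2 h donor 1 had 0.31 with 1 mM (others 0.61 to 0.67) and 0.41 with 4 mM (others 0.99 to 1.09). With 4 mM at 2 h donor 1 also had 1.35 for KLF4 (others 0.44 to 0.56), -0.51 for CXCL8 (others 0.19 to 0.22) and -0.36 for KRT5 (others 0.11 to 0.15). At 6 h donor 1 had -0.25 for FOXJ1 with 0.4 mM (others 0.48 to 0.56), and donor 2 had 1.16 for HMOX1 with 1 mM (others -0.05 to 0.11).

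Single donors also stood apart in list means. Donor 4 had 0.1 for interferon-stimulated genes with 1 mM at 2 h (others -0.13 to -0.098) and -0.026 for hypoxia and glycolysis with 4 mM at 2 h (others -0.216 to -0.208). At 6 h donor 4 had -0.017 for hypoxia and glycolysis with 0.4 mM (others 0.054 to 0.068). For ER stress and the integrated stress response it had -0.093 with 1 mM (others 0.055 to 0.084) and -0.074 with 4 mM (others 0.058 to 0.083). For secretory and mucous cell markers with 4 mM it had -0.556 (others -0.094 to -0.007). Donor 1 had 0.017 for heat shock chaperones with 0.4 mM at 6 h (others 0.05 to 0.054).

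The effect of HOCl differed between 2 and 6 h by limma's test of the difference for 3 genes at 0.4 mM, 16 at 1 mM and 41 at 4 mM. At 0.4 mM the log2 differences were -1.47 for TIPARP, -1.08 for PTGS2 and -0.94 for LPAR6. At 1 mM they were -1.85 for RND1, -1.68 for TIPARP, -1.67 for IL1A, -1.44 for PTGS2 and for MAP3K8, 1.04 for PPP1R3C and 0.84 for MDFI. At 4 mM they were -2.45 for MAP3K8, -2.30 for RND1 and for IL1A, and -1.83 for TIPARP and for FZD10. On the other side at 4 mM stood PPP1R3C with 1.33, DKK1 with 1.31, MDFI with 1.02, PLCXD1 with 1.01 and TENT5A with 0.93.

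Among 1531 tested probe sets with several genes or none listed, which the comparisons of genes left out, 11 passed with 4 mM at 2 h (7 higher, 4 lower, 153 at an unadjusted p under 0.05) and 20 with 4 mM at 6 h (14 higher, 6 lower, 199 unadjusted).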

How the results depend on the processing

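The settings that left out the 2 h control array of donor 1 or the 4 mM array of donor 3 at 6 h, and the donor and time block for the differences between times, were chosen after the data had been seen. No named gene or list mean that had passed reversed under the settings compared. For list means these were the other scalings, the constants of 1 and 64 and the fit without the donor block. Changes of the donor block, the compared groups alone, the variance model and the filter leave the fold changes of genes as they were, so they could not reverse a sign. Genes named for the largest rises or falls had moved the same way in 4 of 4 donors, so leaving out a donor could not reverse them either. With every probe set, the probe set with the smallest p was taken for each gene. Of 4561 values of named genes under other settings, 3974 kept their direction and side of the threshold, 500 no longer passed, 9 passed anew, and 78 that had not passed changed sign. For 600 values of lists these numbers were 561, 12, 6 and 21. Of the 151 named calls, 151 were kept with array weights, 150 with quantile normalization, 143 with array median centring, 143 and 140 with constants of 1 and 64, and 132 without the filter or without the variance trend. Far fewer were kept without the donor block (34) or with the compared groups alone (93). Without donors 1 to 4 in turn 96, 103, 89 and 129 were kept. The calls of CYP1A1 at every dose and time, of CYP1B1 and TIPARP at 2 h and of TXNRD1 and GCLM with 4 mM at 6 h held at all 21 settings. For genes of low intensity, such as TAC1, KHK and CLTCL1, signal near background limited the fold changes, and for genes with several probe sets, such as IL1A, PLCE1 and SCAPER, the mean of probe sets gave smaller ones.

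Without a replicate block the gene counts at 0.4, 1 and 4 mM were 3, 3 and 16 at 2 h and 1, 2 and 11 at 6 h. They were 1 for 4 against 1 mM at 6 h, 1, 1 and 2 for the effects at 6 against 2 h, and 364 for the controls, and 2 lists each were called at 0.4 and 1 mM at 2 h. This setting leaves the differences between donors in the error. With a block by donor and time the counts were 29 at 0.4 mM and 2 h, 7, 13 and 405 at 6 h, 18 for 4 against 1 mM at 6 h, and 8, 28 and 92 for the effects. This block could not be run for the controls at 6 against 2 h, since it absorbs that difference. With the block and only the groups compared, which leaves fewer samples for the error, they were 8, 22 and 40 at 2 h, 4 and 30 at 1 and 4 mM and 6 h, 8 and 25 for the effects at 1 and 4 mM, and 532 for the controls, with 5 lists at 1 mM and 6 h. With the optical density of the RNA as a covariate beside the block the controls gave 683.

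With array weights the counts were 35, 108 and 205 at 2 h, 17 at 1 mM and 6 h, 2 and 19 for 4 against 1 mM at 2 and 6 h, and 5, 28 and 70 for the effects, with 3 lists at 1 mM and 2 h. The count at 1 mM and 6 h was 5 with a pseudocount of 64, 5 without the filter on low values, 4 without the variance trend, 5 with the mean of probe sets and 5 with every probe set. The count at 0.4 mM and 6 h was 5 with a pseudocount of 64, and that of the effect at 1 mM was 10 with every probe set. At 1 mM and 2 h 3 lists were called after quantile normalization and 3 without the filter. With an estimated correlation camera called 1, 1 and 1 lists at 2 h and 0, 0 and 1 at 6 h, and fry called 1, 1 and 3 at 2 h and 0, 0 and 4 at 6 h. Of these values the cause was not tested unless stated. Quantile normalization changed the split into higher and lower genes to 2 and 2 at 0.4 mM and 6 h (1 and 2 as reported), 6 and 2 at 1 mM and 6 h (5 and 3), and 8 and 4 for 4 against 1 mM at 6 h (7 and 1). The list tests were not run with every probe set or with robust eBayes.

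Leaving out each donor in turn, which leaves fewer samples, gave 7 to 20 genes at 0.4 mM, 22 to 35 at 1 mM and 53 to 115 at 4 mM at 2 h, and 1 to 3, 2 to 7 and 68 to 165 at 6 h. It gave 0 to 0 for 1 against 0.4 mM at both times, 0 to 4 and 3 to 11 for 4 against 1 mM at 2 and 6 h, 0 to 3, 4 to 12 and 18 to 46 for the effects, and 774 to 1440 for the controls. The lists called were 3 to 6, 3 to 5 and 5 to 8 at 2 h and 3 to 5, 3 to 5 and 4 to 6 at 6 h. Without the 2 h control array of donor 1 the gene counts were 11, 24 and 99 at 2 h and 3, 10 and 345 at 6 h, 0 and 12 for 4 against 1 mM, 2, 10 and 31 for the effects and 1205 for the controls, with 3, 4 and 7 lists at 2 h and 4, 3 and 6 at 6 h. Without the 4 mM array of donor 3 at 6 h they were 15, 57 and 135 at 2 h and 3, 8 and 193 at 6 h, 0 and 5 for 4 against 1 mM, 2, 17 and 47 for the effects and 1755 for the controls, with 5, 5 and 5 lists at 2 h and 4, 3 and 7 at 6 h.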

Other observations

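Between the untreated cultures of 2 and 6 h, many genes of the cell cycle and of cholesterol synthesis were lower at the later time. Of 35 cell cycle genes 21 fell and 0 rose (23 lower adjusted over the list alone, list mean -0.444), among them the replication licensing gene MCM2 (-1.07) and the nucleotide synthesis genes RRM2 (-0.98) and TYMS (-0.89). Of 20 genes of cholesterol synthesis 12 fell and 0 rose (14 lower adjusted over the list alone, list mean -0.329), with FASN at -0.71, IDI1 at -0.68 and HMGCS1 at -0.60. Of 31 genes of ER stress and the integrated stress response 11 fell and 3 rose (13 and 5 adjusted over the list alone), with PSAT1 at -0.94, TRIB3 at -0.82 and NUPR1 at 0.89. Of 27 proteasome genes 7 fell and 0 rose (10 lower adjusted over the list alone). Of 28 interferon-stimulated genes 9 rose and 0 fell (12 higher adjusted over the list alone, list mean 0.498), and of 30 NF-kB targets 7 rose and 0 fell (8 higher adjusted over the list alone). No list test was run for this comparison, so these are counts of genes only, and the optical density of the RNA differed between the groups as well.

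The other lists were counted in the same way, with no test of a difference between lists. Higher and lower genes at 6 h numbered 5 and 5 of 34 for immediate early genes, 3 and 2 of 33 for NRF2 targets, 4 and 2 of 22 for heat shock chaperones, and 3 and 3 of 19 for p53 targets. They numbered 6 and 3 of 24 for wound repair, 4 and 5 of 26 for hypoxia and glycolysis, 2 and 2 of 35 for oxidative phosphorylation, and 2 and 3 of 15 for the AhR list. For markers of cell types they numbered 3 and 0 of 21 for ciliated, 3 and 2 of 17 for basal, 3 and 0 of 17 for squamous, 0 and 0 of 24 for secretory and 2 and 0 of 7 for fibroblast markers. The metallothioneins had 0 higher and 1 lower of 8. Of 3 leukocyte markers 1 fell (3 lower adjusted over the list alone), which was CD14 at -0.55 (adjusted p = 0.00476), and 2 endothelial markers had a mean of 0.154.

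Regrouping the samples in other ways was a test fixed for all counts, with its reading written after the results were seen. Over 35 splits of the samples, most of which put both samples of some donors on the same side, 1 split, the real one, gave as many genes for each dose at 2 h (14, 53 and 118 genes, highest other split 6, 1 and 7) and for 1 and 4 mM at 6 h (8 and 228, highest other 0 and 3). The same held for 4 against 1 mM at 6 h (8, highest other 2) and for the controls at 6 against 2 h (1604, highest other 19). Most of these splits ignore the donors, which pair the samples, and the splits within donors are too few, so this test could not exclude chance for these counts. For 0.4 mM at 6 h 2 of 35 splits gave as many (3, highest other 27), so chance was not excluded. The other split did not part the samples of all donors, and its 27 genes point to some structure of the samples, which was not identified. For the dose steps with 0 genes called by limma, 35 of 35 splits gave as many, which a count of 0 fixes in advance, so this tests nothing. The highest other counts were 0 and 0 at 2 h and 4 at 6 h. In these steps 210, 254 and 196 genes had an unadjusted p under 0.05, fewer than the 426.4 of chance.

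For the difference of effects between times, 8 of 100 splits gave as many genes at 0.4 mM (3, highest other 21), 1 of 100 at 1 mM (16, highest other 15) and 4 of 100 at 4 mM (41, highest other 116). Most of these splits ignore the donors and some keep a sum of the effects at both times, so chance was not excluded at any dose. Among the 8 splits at 4 mM that part the samples of all donors 4 gave as many genes, the real one included. The other 3 of these exchanged treated and control samples in all donors at 2 h and in 1 donor at 6 h, so they measure a sum of the effects at both times, a structure of the samples, and give no reference without change. For the number of lists called, 15, 6 and 12 of 35 splits gave as many at 0.4, 1 and 4 mM at 2 h (4, 5 and 5 lists, highest other 7 each). At 6 h 19, 15 and 6 of 35 splits did (4, 3 and 6 lists, highest other 10, 5 and 6). Chance was not excluded for any of these 6 numbers of lists.

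The donors pair the samples, so the real splits were also compared with the splits that part the samples of all 4 donors, 8 in each case and 5 for the effect at 0.4 mM, too few for a share under 0.05 when the real one is counted. Among these the highest other gene counts were 0, 0 and 4 for 0.4, 1 and 4 mM at 2 h, 0, 0 and 3 at 6 h, 0 for 4 against 1 mM at 6 h and 5 for the controls. For the effects they were 0, 1 and 116, and for the lists 3, 4 and 7 at 2 h and 2, 3 and 6 at 6 h.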
